A study of Homo sapiens with 37 samples.

How the data were processed

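RNA was labelled in HEK293T cells, a human embryonic kidney line, by APEX fusion proteins, peroxidases that attach biotin-phenol to nearby RNA. The labels give 500 µM biotin-phenol for 30 min, then 1 mM H2O2 for 1 min, extraction with TRIzol and enrichment of biotinylated RNA on streptavidin beads. The pulldown is the bead-bound RNA and the input is the RNA of the same kind of cells; libraries were made with a directional kit from NEB, per the labels. The 37 libraries fall into 20 from unstressed cells carrying 1 of 5 constructs (naive table) and 17 from cells carrying APEX-eIF4A, at T0 without stress or under heat shock, hippuristanol or DMSO (stress table).

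The deposited values are raw whole-number counts per versioned Ensembl gene ID, 60483 IDs in each table. Per the submitters' processing notes, the authors used cutadapt, HISAT2 and featureCounts with GRCh38 to make these counts; versions, the strand setting and the treatment of reads that match several genes are not given in the sources used here. IDs that share reads with a near-identical copy or overlap another gene are therefore uncertain. The libraries carry no molecular identifiers in the labels, so amplified copies count as separate reads.

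Groups and replicate numbers were taken from sample titles. Hippuristanol inputs were grouped by title, although their stress label reads heat shock. One column name occurs in the descriptions of 2 samples; it was read as the second naive eIF4A input in the naive table and as the DMSO input in the stress table, and those columns differed (correlation of log2(count + 1) across IDs, 0.918; IDs are not independent replicates). The unit of T in T0, T4 and T20 is not given in the labels. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicate pairs were compared by chi-square over IDs with at least 10 counts in the pair; the statistic per ID was 1.31 to 77.3, and no pair held identical values. Deviations of same-numbered inputs and pulldowns correlated between -0.07 and 0.14 across IDs, and no label ties the numbers to a shared culture or day. Between stress-table inputs, same-numbered deviations correlated at 0.636 for T20 with hippuristanol but at -0.787 for T0 with hippuristanol and -0.699 for T0 with T20, over 4369 IDs, so these inputs share structure that the numbers as given do not follow. The numbers were not taken to pair libraries, and T20 over T0 in inputs was also fitted with them crossed.

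Each table was tested separately with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, estimateDisp, robust glmQLFit and the 2-sided quasi-likelihood F test, with a mean per group over all libraries of a table and Benjamini-Hochberg adjustment. IDs at an adjusted p under 0.05 are called. This left 12427 IDs in the naive table and 16678 in the stress table. Input-adjusted comparisons are the difference between pulldown-over-input contrasts. The standard error of a log2 fold change was its size divided by the square root of F. Log2 CPM values used a prior count of 2, and correlations used IDs with a mean log2 CPM of at least 5. Alternatives were library size in place of TMM, DESeq2 1.42.0, no count filter, only the libraries compared, a replicate block, no input correction, and each library left out in turn; groups, tests and these alternatives were fixed before the data were examined.

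The edgeR step was tested on simulated counts with 200 changed IDs for each comparison. For CBX1 pulldown over input, run on 11838 IDs, 22.4% of 2-fold, 73.1% of 4-fold and 84.8% of 8-fold changes were recovered; for CBX1 over GFP, input-adjusted, the shares were 4.48%, 34.3% and 56.1%. In the stress table, the input-adjusted comparison of T20 with T0, run on 14486 IDs, recovered 0% of 2-fold and 4-fold and 9.09% of 8-fold changes. The T20 input comparison, on 14475 IDs, recovered 0%, 0% and 19.7%, and hippuristanol over DMSO, on 14490 IDs, 0%, 2.99% and 13.6%. Simulated inputs took the spread estimated over inputs and pulldowns together, although replicate inputs resembled each other more than replicate pulldowns did. The shares for the T20 input comparison therefore describe inputs with that common spread, not the inputs by themselves.

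The gene table used here, made for assembly GRCh38.p14, holds no Ensembl IDs, so 0 IDs matched and the files do not pair IDs with names. The 19 gene lists fixed in advance, the markers of other cell types and the rule for named genes, which skips IDs without a symbol, could not be applied. At most 2 IDs that rose and 2 that fell are printed, chosen after their values were seen: from IDs with a mean log2 CPM of at least 3 and no overlap between replicates of the sides compared, the one most often among the leading changes over the 5 constructs and the leading one of the CBX1 comparison with GFP, in each direction.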

Results

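The naive libraries covered APEX-CBX1, C1-APEX, APEX-GFP, APEX-eIF4E and APEX-eIF4A, each with 2 inputs and 2 pulldowns. CBX1 is a chromatin protein, eIF4E binds the mRNA cap and eIF4A is the RNA helicase of the same initiation complex; the GFP fusion served as the construct without such a partner. Total counts were 1419968 to 2629957 in the 10 naive inputs and 1718517 to 3276410 in the 10 naive pulldowns. In the stress table the 8 inputs held 4540426 to 7782943 counts and the 9 pulldowns 707356 to 1221213, so pulldown values there rest on fewer counts. T0, T20 and hippuristanol had 2 libraries per fraction; T4 had 1, and DMSO had 2 pulldowns and 1 input.

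A few IDs took most counts of the naive libraries. The 10 highest IDs of the table held 71.8% ± 2.50 of counts in inputs (SD, n = 10) and 62.2% ± 4.46 in pulldowns (SD, n = 10). The difference was 9.64 percentage points (2-sided permutation test, 100000 permutations, p = 5.0e-05), with a lower mean in the pulldown of 5 of 5 constructs. The test took the 20 libraries as independent, although they are 2 per group and replicates resembled each other. Inputs held 74.6% ± 0.98 for eIF4A and 69.1% ± 0.60 for GFP (SD, n = 2). The p is therefore too small for a statement about constructs, which rests on the 5 of 5 lower means.

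The first comparison asked which RNAs each construct's pulldown held above or below its own input. ENSG00000245848.2 was higher in the pulldown of all 5 constructs. Its normalised level in inputs was 11.2 ± 1.06 to 18.1 ± 6.75 CPM, against 1013 ± 145 CPM in the eIF4A, 2314 ± 979 in the CBX1, 2489 ± 2469 in the eIF4E, 2813 ± 520 in the GFP and 10553 ± 8448 in the C1 pulldown (SD, n = 2 each). The log2 fold change ran from 6.19 ± 1.04 (SE) for eIF4A to 9.88 ± 1.14 for C1 (edgeR adjusted p = 0.0116 and 0.00109). ENSG00000200312.1 was lower in the pulldown of all 5 constructs, by a log2 fold change of -1.995 ± 0.302 for CBX1 to -5.01 ± 0.35 for eIF4E (edgeR adjusted p = 0.000214 and 7.23e-11). In the GFP libraries it fell from 55.8 ± 1.25 to 4.27 ± 2.60 CPM (SD, n = 2). Leaving out single libraries changed some of these folds by over 1.5 times on the linear scale, given here as log2 fold changes. For ENSG00000245848.2, C1 gave 8.66 without pulldown replicate 1 and 10.49 without replicate 2, and eIF4E, at 7.13, gave 5.40 and 7.91, so the lowest construct changed. For ENSG00000200312.1, GFP went from -3.66 to -4.50 without pulldown replicate 2 and eIF4E from -5.01 to -4.33 without input replicate 2. The call of ENSG00000245848.2 was lost in 2 of 4 fits with 1 library left out for CBX1, 2 of 4 for eIF4E and 3 of 4 for eIF4A, and for eIF4E also with only the libraries compared (log2 fold change 7.10, edgeR adjusted p = 0.265).

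C1 gave 802 called IDs, 359 higher and 443 lower in the pulldown. GFP gave 502 (242 higher, 260 lower), CBX1 486 (199 higher, 287 lower), eIF4E 312 (152 higher, 160 lower) and eIF4A 271 (144 higher, 127 lower). The median log2 fold change of the higher IDs was 1.41 for CBX1, 1.30 for C1, 0.99 for GFP, 0.95 for eIF4E and 0.94 for eIF4A. With only the libraries compared, C1 gave 15 (5 higher, 10 lower), GFP 704, CBX1 860, eIF4E 423 and eIF4A 722, so the order of the constructs depended on the setting. The count of each construct changed when single libraries were left out. Such a fit leaves 1 library in a group, so a lower count may reflect lost power. It does not show that the count rested on the library left out. The change was smallest without pulldown replicate 2 for CBX1 and eIF4E and without pulldown replicate 1 for C1. Those fits are not among the values given next for the count of each construct. Without input replicate 1 or 2 it was 85 or 149 for CBX1, 158 or 176 for C1, 140 or 185 for GFP, 166 or 99 for eIF4E and 88 or 91 for eIF4A. Without pulldown replicate 1 it was 86 for CBX1, 284 for GFP, 116 for eIF4E and 149 for eIF4A; without pulldown replicate 2 it was 218 for GFP, 97 for eIF4A and 3246 for C1. The balance of directions depended on scaling. With library size in place of TMM, the median over tested IDs moved from 0.02 to 0.41 for CBX1, 0.01 to 0.18 for C1, 0.00 to 0.24 for GFP, 0.02 to 0.89 for eIF4E and 0.02 to 0.82 for eIF4A, and higher IDs made up 93.2%, 69.2%, 85.2%, 98.6% and 98.6% of calls, against 40.9%, 44.8%, 48.2%, 48.7% and 53.1% with TMM. Fold changes are therefore relative to the TMM reference.

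**Figure D1:**
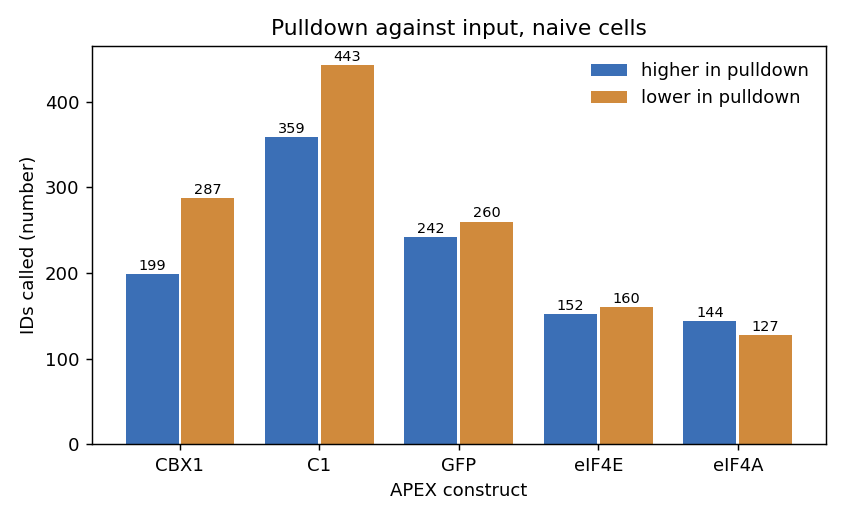
Number of IDs called between pulldown and input in naive cells for each construct, higher (blue) or lower (orange) in the pulldown, from 2 libraries per group. With TMM and all naive libraries fitted, C1 has 359 higher and 443 lower and eIF4A 144 and 127; the order differs with only the libraries compared (C1 15, eIF4A 722) and with library size (C1 763, eIF4A 3940).

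The calls overlapped between constructs, whose libraries were separate. Of 1443 IDs called in at least 1 construct, 17 were higher in all 5 and 43 were lower in all 5, where independent lists would give 1.59e-05 and 2.82e-05; 962 were called in 1 construct and 2 in opposite directions. GFP and eIF4E shared 97 higher IDs against 2.96 for independent lists, and CBX1 and eIF4E shared 25 against 2.43. These expectations take every tested ID as equally easy to call. IDs with more counts are easier to call, and the 5 tests shared the estimate of spread of each ID. Part of the excess is therefore built in, by an amount that was not measured. For the 2 IDs called in opposite directions no expected number was computed. Across 2099 IDs, pulldown-over-input profiles of the same construct correlated at a mean of 0.721 and those of different constructs at 0.608. That was the highest mean of the 945 ways to pair the 10 profiles, with same-numbered inputs and pulldowns joined (one-sided exact test, p = 0.00106, the smallest it can give; adjusted over 3 profile kinds, 0.00106). It was not the highest with the inputs' numbers crossed (exact p = 0.00529) or over IDs with a mean log2 CPM of at least 7 (exact p = 0.00317). Inputs gave 0.978 and 0.940, and pulldowns 0.952 and 0.904, each with an exact p of 0.00106. The mean did not hold for each construct: the C1 replicates correlated at 0.559, below C1 with GFP (0.629) and C1 with eIF4A (0.568), and the eIF4E replicates at 0.743, below eIF4E with eIF4A (0.771). The mean correlation was 0.493 between CBX1 and eIF4A; IDs are not independent replicates.

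The second comparison asked where a construct's pulldown over input differed from that of GFP. CBX1 differed in 20 IDs, 17 higher and 3 lower (edgeR). ENSG00000269821.1 had the largest increase, a log2 difference of 2.69 ± 0.41 (SE; edgeR adjusted p = 0.00567). It measured 95.5 ± 32.7 CPM in the CBX1 pulldown and 48.7 ± 1.51 in the GFP pulldown, with 8.93 ± 1.95 and 29.4 ± 3.36 in the inputs (SD, n = 2). Without input correction its log2 difference was 0.978, so the larger part of the 2.69 lay between the inputs. The CBX1 inputs held only 12 and 17 counts of this ID, and the inputs of the other constructs measured 29.4 to 49.9 CPM. Its level in the CBX1 pulldown lay near those of eIF4E (84.9 ± 25.1 CPM) and C1 (70.5 ± 11.2), while eIF4A (47.4 ± 6.17) lay near GFP (SD, n = 2). ENSG00000130726.10 had the largest decrease, -0.90 ± 0.17 (SE; edgeR adjusted p = 0.0282). With 1 library left out, the call of ENSG00000269821.1 was lost in 3 of 8 fits and that of ENSG00000130726.10 in 7 of 8. The latter was also lost with library size in place of TMM and without a count filter, which called 25 and 30 IDs, all higher. The count of 20 fell to 0 without CBX1 input replicate 1, GFP input replicate 1 or GFP pulldown replicate 1, and to 2, 2 and 3 without CBX1 input replicate 2, CBX1 pulldown replicate 1 and GFP input replicate 2. DESeq2 called 44, 19 higher and 25 lower, and gave ENSG00000269821.1 a log2 difference of 2.68 but no adjusted p, since its mean count was under the tool's filter.

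Called IDs numbered 0 for C1, eIF4E and eIF4A against GFP and for eIF4A against eIF4E (edgeR). Of 12427 tested IDs, 1045, 472, 411 and 251 had an unadjusted edgeR p under 0.05. Only the 1045 for C1 lay above the share of 0.05 that arises without any change. For CBX1 against GFP the number was 912, also above that share but lower than for C1. The 20 calls for CBX1 against 0 for C1 therefore do not show that CBX1 differed more widely from GFP. DESeq2 called 0, 15, 16 and 0 IDs for C1, eIF4E and eIF4A against GFP and for eIF4A against eIF4E. The 15 for eIF4E were all lower than in GFP, whereas library size in place of TMM gave 43, all higher. The C1 count was 14 without C1 pulldown replicate 1 and 993 without C1 pulldown replicate 2; the eIF4A count against GFP was 7 without eIF4A pulldown replicate 1. Without input correction, pulldowns differed from GFP in 190 IDs for CBX1, 833 for C1, 678 for eIF4E and 204 for eIF4A, and eIF4A from eIF4E in 269. The inputs of the same constructs also differed, in 11, 41, 346, 72 and 92 IDs, of which 7, 32, 211, 52 and 64 were among the pulldown calls. Over the IDs called between pulldowns, the median ratio of input to pulldown log2 difference was 0.138 for CBX1, 0.303 for C1, 0.684 for eIF4E, 0.659 for eIF4A and 0.795 for eIF4A against eIF4E.

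**Figure D2:**
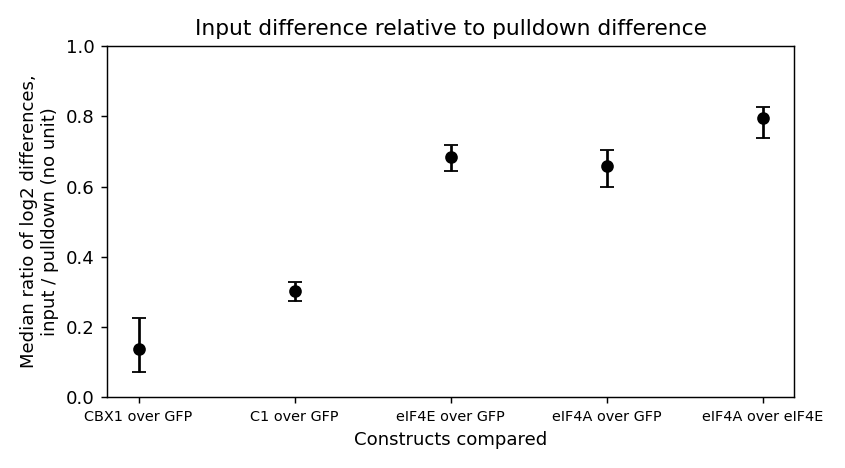
Median ratio of the input log2 difference to the pulldown log2 difference over IDs called between pulldowns, for 5 pairs of constructs; bars are 95% bootstrap intervals over IDs, which are not independent. The ratio is 0.138 for CBX1 over GFP and 0.795 for eIF4A over eIF4E.

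The third comparison asked what heat shock changed at T20 relative to T0. In inputs, 3 IDs rose and 4 fell (edgeR). Of 16678 tested IDs, 228 had an unadjusted p under 0.05, below the share of 0.05 that arises without any change. The test took 1 spread per ID over inputs and pulldowns. Replicate inputs correlated at 0.943 to 0.966 over tested IDs and replicate pulldowns at 0.613 to 0.730. The test was therefore cautious for inputs, and the 7 calls do not estimate how many RNAs changed. The median level of those that rose was 7.92 log2 CPM at T0, 8.53 in the single T4 library and 10.83 at T20; in pulldowns it was 8.34, 8.29 and 10.50. The 4 that fell had log2 counts correlated at 0.9996 or above over the 17 libraries and are uncertain, since near-identical copies can share reads. Those libraries join inputs and pulldowns, in which the median level at T0 was 4.33 and 16.74 log2 CPM. Much of the correlation therefore reflects that gap, and none was computed within inputs or within pulldowns. These 4 IDs made up at most 0.00777% of counts in an input but 15.9% to 30.7% in pulldowns. In the naive table they took 4.11% to 6.43% of counts in inputs and pulldowns alike. The fall was thus measured on a very small share of input counts. Stress inputs differed in make-up from naive inputs and from stress pulldowns, which limits comparisons of pulldown with input in the stress table. The cause was not tested. The input count depended on the setting: with only the T0 and T20 inputs it was 379, 375 higher, and with DESeq2 22, all higher. Same-numbered T0 and T20 inputs deviated in opposite directions (correlation -0.699 across 4369 IDs, which are not independent). With the numbers crossed as a block it was 3, all higher, and 2069 with only the T0 and T20 inputs. It was 0 without T0 input replicate 2 and 4, 3 and 1 without T0 input replicate 1, T20 input replicate 1 and T20 input replicate 2. Input-adjusted, 0 IDs were called (edgeR), 1226 had an unadjusted p under 0.05, and DESeq2 called 82. On simulated counts this test recovered no 4-fold change, so the 0 says little about changes of that size.

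Hippuristanol, an inhibitor of eIF4A, was compared with DMSO in pulldowns. No ID was called (0 by edgeR), and the smallest edgeR adjusted p was 0.0534. Of 16678 tested IDs, 2394 had an unadjusted p under 0.05, above a share of 0.05. DESeq2 called 797, 639 higher and 158 lower. The 2 DMSO pulldowns correlated at 0.543 over IDs with a mean log2 CPM of at least 5, the lowest of all replicate pairs. On simulated counts the edgeR test recovered 2.99% of 4-fold changes, so the 0 says little about changes of that size. The count was 7 without DMSO pulldown replicate 1 and 14 without DMSO pulldown replicate 2. In inputs, where DMSO had 1 library and no test was made, 95.7% of 4369 IDs lay within 0.5 log2 units of DMSO.

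**Figure D3:**
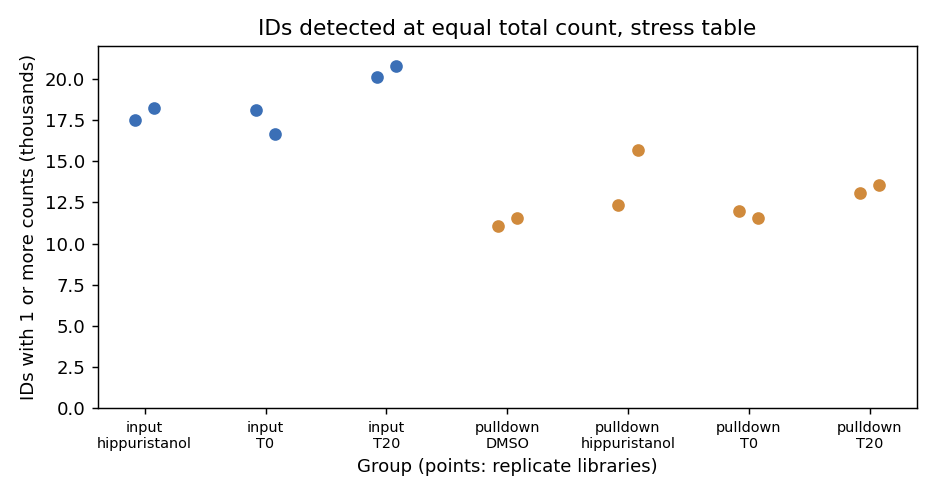
IDs with at least 1 count in each replicated stress library after thinning every library to 707356 counts, inputs in blue and pulldowns in orange. The inputs lie between 16650 and 20793 IDs and the pulldowns at or below 15705.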

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

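The tests on C1 pulldown replicate 1 and on the stress-table pulldowns, the separation of the input ratios by comparison and their bootstrap intervals were chosen after the results were seen; the bounds of the input ratios were written before.

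CBX1 and GFP differed in pulldown over input in 20 IDs, by a test of the difference itself. Pulldowns of different constructs differed in many more IDs before input correction than after it. The ratio of the input difference to the pulldown difference and the remaining, input-adjusted ratio sum to 1, so they are a single measurement. For eIF4E over GFP, eIF4A over GFP and eIF4A over eIF4E the ratios were 0.684, 0.659 and 0.795, which fits differences in total RNA between the cell populations, and the remaining 0.316, 0.341 and 0.205 argue against lost power alone; unlabelled RNA carried into the pulldowns could give the same ratio and was not tested. For CBX1 over GFP the ratio of 0.138 argues against total RNA as the main source of the 190 calls between pulldowns. Choosing IDs by their pulldown difference lowers such a ratio, by an amount that was not measured. The ratio does not cover the 20 input-adjusted calls: ENSG00000269821.1 differed by 2.69 input-adjusted but by 0.978 between pulldowns. The remaining 0.862 leaves lost power open because its interval reaches below the bound of 0.8. For C1 over GFP, 0.303 and 0.697 fall between the bounds, so the explanations cannot be told apart, and a difference between the constructs stays open in each case.

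C1 pulldown replicate 1 correlated with its partner at 0.761 over tested IDs, against 0.904 to 0.951 for the other naive pulldown pairs. Fewer counts cannot account for this: with pulldowns thinned to equal totals the lowest of the other pairs was higher by 0.214, and with equal counts outside the 10 highest IDs it was 0.886 against 0.649. Few distinct molecules may contribute, but the test changed sign with depth. The library detected -299 IDs relative to the lowest other pulldown with whole libraries thinned, and -319 without the 10 highest IDs. At a lower depth it detected 160 more. With whole libraries thinned, 1 ID had at least 50 counts here and at most 1 in its partner. Counting either direction, the pair held 4 such IDs unthinned and 2 thinned without the 10 highest, against 0 in the other naive pulldown pairs. These are too few to decide. A naive library of another group under this label could not be decided on. The best match among libraries of other groups was 0.735, below the lowest of their partner correlations by 0.161 over the same IDs of thinned libraries. Without the 10 highest IDs it was lower by 0.174. A noisy library of any group could fall short of those correlations, as this library did with its labelled partner (0.724). A sample from outside the naive libraries also stays open. The correlation of C1 pulldown replicate 1 with its partner minus that with its best match was -0.0113. Among inputs, however, this library correlated best with the 2 C1 inputs, at 0.711 and 0.709 against 0.663 to 0.685 for the others. Without the 10 highest IDs the values were 0.694 and 0.690 against 0.642 to 0.666. This order goes with the stated label, but no sample from outside was compared. No biological explanation was tested.

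Replicate pulldowns of the stress table correlated at 0.613 to 0.730 over tested IDs and inputs at 0.943 to 0.966. Lower depth does not account for this: with libraries thinned to 707356 counts, the lowest input pair was above the highest pulldown pair by 0.275 over IDs with at least 20 counts in a pair, and without the 10 highest IDs, over a single set of IDs, by 0.156. Few distinct molecules, each read many times, is consistent with the IDs detected in DMSO, T0 and T20 pulldowns, at most 11561, 12005 and 13560 against at least 16650 in thinned inputs, and also without the 10 highest IDs, at most 11143, 11718 and 13173 against at least 14655. For hippuristanol it stays open, since the pulldowns detected at most 15705 IDs with whole libraries but 15076 against 14655 in the lowest input without the 10 highest. A pulldown that truly holds fewer RNA species could also detect fewer IDs, and that was not tested.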

How the results depend on the processing

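Library size alone gave 911 calls for CBX1, 4525 for eIF4E and 3940 for eIF4A over input, and 1 for C1 and 43 for eIF4E over GFP. DESeq2 gave 44 for CBX1, 15 for eIF4E and 16 for eIF4A over GFP, 82 for T20 input-adjusted, 22 for T20 input and 797 for hippuristanol. Without a count filter the counts were 3, 16 and 19 for C1, eIF4E and eIF4A over GFP, 1 for T20 input-adjusted, 4 for T20 input and 31 for hippuristanol. For eIF4E over GFP the 43 were all higher and the 15 and 16 all lower. Library size moved the median log2 difference over tested IDs from 0.03 to 0.65, a shift of all IDs towards higher. Whether the 43, 15 and 16 share IDs was not examined, so the counts do not show that any ID changed direction. With only the libraries compared they were 860, 15 and 722 for CBX1, C1 and eIF4A over input, 38 for CBX1 over GFP and 379 for T20 input. Without input correction they were 190, 833, 678 and 204 for CBX1, C1, eIF4E and eIF4A over GFP, 269 for eIF4A over eIF4E and 24 for T20. The replicate block, for numbers not taken to pair the libraries, gave 329 for T20 input and 11 for T20 input-adjusted, and moved no other count by over 1.5 times. These fits also left out libraries: without a block such fits gave 379 and 0, and with all libraries the block gave 8 and 3. For T20 input, crossing the numbers, whose deviations correlated at -0.699, gave 3 with all libraries and 2069 with only those compared; these fits with all libraries, the crossed ones and the one without a block for T20 input-adjusted were chosen after seeing the data. Except where a setting's construction shows it (fewer libraries or another contrast), the cause was not tested.

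With each library left out in turn, its lone partner assumed to vary like the other groups, calls over input ranged from 85 to 431 for CBX1, 158 to 3246 for C1, 140 to 284 for GFP, 99 to 401 for eIF4E and 88 to 149 for eIF4A. Over GFP they ranged from 0 to 22 for CBX1, 0 to 993 for C1 and 0 to 7 for eIF4A; T20 input gave 0 to 4 and hippuristanol 0 to 14. eIF4E over GFP, eIF4A over eIF4E and T20 input-adjusted stayed at 0 in these fits. Of the values for single IDs and for profile correlations, 104 kept their direction and side of the threshold, 20 kept direction only and none reversed; DESeq2 gave no adjusted p for ENSG00000269821.1, which is not counted there. The gene-list alternatives were not run, since no ID has a name here. In the stress table, pulldowns of 707356 to 1221213 counts give less precise values for low-count IDs than the inputs.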

Other observations

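The profile comparisons and the values in this part were chosen after the data were examined.

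Pulldown over input at T0 in the stress table and in naive eIF4A cells, both APEX-eIF4A without stress, correlated at 0.07 across 1988 IDs; the other 4 constructs gave -0.01 to 0.06 against T0. The tables were normalized separately, which shifts all IDs nearly alike and so changes a correlation little. They also differed in make-up: the 10 highest IDs of each held a mean of 71.8% of counts in naive inputs and 9.85% in stress inputs. The 2 T0 pulldowns correlated at only 0.601 over IDs with a mean log2 CPM of at least 5. The low value therefore cannot be read as eIF4A labelling that failed to repeat, and its cause was not tested. DMSO and T0 pulldowns differed in 85 IDs, 24 higher and 61 lower in DMSO (edgeR). In the naive table, the 4 IDs that fell in heat-shocked inputs took 4.11% to 6.43% of counts.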
